A study of Oryzias latipes with 7 samples.

How the data were processed

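Gene expression was measured in isolated ovarian follicles of medaka kept at 27 °C under 14 h of light and 10 h of dark. Per the labels, the largest and second-largest follicles were isolated at each sampling time, RNA of 100 follicles per stage was extracted with a column kit with DNase digestion, and cDNA was labelled with Cy3 by random priming for 1-colour NimbleGen arrays. Each of the 7 time points has 1 array.

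The values are intensities that the authors deposited as RMA expression values, per the file headers and the submitters' processing notes. RMA in general corrects background, normalizes between arrays and summarises the probes of a probe set. The version and settings are not given in the sources used here. The deposited intensities are on a linear scale, and each file also gives the number of probes per probe set, from 1 to 6 (6 in 99.3% of probe sets). No replicates were pooled in the files beyond the follicles themselves. The deposited series table holds the same intensities, equal within 0.001 intensity units in all probe sets, but places 5 of the 7 arrays under another sample than the per-array files do. Its columns run in ascending order of array number. The per-array files were used, as planned before the data were examined, and the series table's times were an alternative. The values carry no detection call, so no detection limit was set, and the filter described below used a percentile of the mean level instead. The deposited arrays do not share one distribution, with medians from 599 to 703, and all 3 arrays of the 8-digit series have lower medians than all 4 of the 6-digit series. An overall change in RNA content per follicle was not assessed.

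Each array was assigned to its time by its developmental stage label. Intensities were put on the log2 scale, and probe sets with a mean log2 value over the 7 arrays at or below the 25th percentile (6.24) were left out. This kept 47773 of 63698. The slope on hours before spawning and the step between 23 h and 14 h were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) over all 7 arrays with the array-number series (6 or 8 digits) as a term, and p-values were adjusted by the Benjamini-Hochberg method. A slope is given as the fitted log2 change over the 45 h from 47 h to 2 h, positive where expression was higher nearer spawning. All p-values measure the spread of single arrays about the fitted line or step, and the number of arrays limits the precision. Consecutive intervals, 24 h pairs and single-time-point highs and lows (a gap of at least 2 on the log2 scale to all other arrays) were counted without a test, using Python 3.11.15 with pandas 2.3.3. Correlations and principal components were computed on the filtered log2 values.

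The fits were tested on simulated data with the real probe set means, the fitted variances and 200 changed probe sets among 47773. For the slope, 0 of 50 probe sets with a simulated log2 change of 1 were called, 3 of 50 with 2, 32 of 50 with 4 and 44 of 50 with 6, together with 9 unchanged probe sets. For the step, 1 of 50, 24 of 50, 43 of 50 and 45 of 50 were called, with 9 unchanged probe sets. The simulated noise was independent between probe sets, with no effect of the array-number series and no change of another shape. These shares may therefore not hold for the real arrays.

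The tests, the array-number term, the filter and 31 lists of genes (827 entries, among them markers of granulosa, theca, blood, immune, endothelial, liver and muscle cells) were set before the data were examined. The lists and the rule for named genes needed gene symbols. The probe set identifiers matched no entry of the reference gene table used here, so neither was applied, and marker levels of other cell types are not reported. In place of named genes, the 2 probe sets with the largest called rise and the 2 with the largest called fall in the slope test are given by identifier. Genome positions are not given for the same reason. Alternatives tried were the array-number term, the filter, renormalization, centring, an offset of 64 before the logarithm, another variance prior, the rank of time, 5 h for the last array, other step positions, other fold limits, leaving out each array and the times of the series table. Added after the data were seen were the profile groups over runs of neighbouring times, the series table's times for all counts without a test and for both fits without the array-number term, the centred intervals, the quantile normalized single-time-point counts and a paired limma fit of the 24 h pairs.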

Results

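Ovarian follicles of medaka (Oryzias latipes), a small teleost fish that spawns daily under long days, were profiled as they approached spawning. A follicle is an oocyte with the granulosa and theca cells that surround it. Total RNA of 100 pooled follicles per stage was hybridised to a 1-colour (Cy3) NimbleGen expression array at 47, 35, 32, 23, 14, 8 and 2 h before spawning, with 1 array per time point and 7 arrays in all. The series title places these stages in late vitellogenesis, oocyte maturation and the period before ovulation. Each array reported an RMA intensity for 63698 probe sets, of which 47773 lay above the filter on low values. The median intensity of an array over all probe sets ranged from 599 at 8 h to 703 at 47 h. No time point had a replicate, so differences between 2 time points are given as values without a test. The probe set identifiers are not paired with gene names in the files used here, so results are given for groups of probe sets.

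The time of 5 of the 7 arrays differed between the deposited sources. The 7 columns of the series table equalled the 7 per-array files value for value, but only the 47 h and 8 h columns equalled the file of the same sample. The array filed under 35 h stood in the table under 2 h, and the array filed under 32 h stood under 14 h. The array filed under 23 h stood under 35 h, that filed under 14 h under 32 h, and that filed under 2 h under 23 h. Times below are those of the per-array files, and the main counts with the times of the series table are given beside them. For the 2 h sample, 1 label field gives 5 h in place of 2 h. The array numbers fell into 2 series, one of 6 digits (47, 23, 14 and 2 h) and one of 8 digits (35, 32 and 8 h), which were treated as a possible batch.

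Arrays were compared first to see how far the follicle transcriptome moved with time. The 47, 35 and 32 h arrays resembled one another, with Pearson r across probe sets of 0.955 for 47 and 35 h, 0.960 for 47 and 32 h and 0.976 for 35 and 32 h. The 23 h and 14 h arrays formed another close pair at r = 0.957. The 8 h array correlated with the other arrays at 0.841 to 0.892 and the 2 h array at 0.842 to 0.874. These correlations are across probe sets, which are not independent replicates. Component 1 of a principal component analysis held 38.9% of the variance and ran from 0.40 at 47 h to -0.65 at 2 h, passing through -0.03 at 14 h. Component 2, with 27.7%, set the 23 h and 14 h arrays (-0.41 and -0.64) against the 35 h array (0.41) and the 2 h array (0.39). Component 3, with 20.4%, was negative in the 3 arrays of the 8-digit series and positive in the 4 arrays of the 6-digit series, and was led by the 8 h (-0.70) and 2 h (0.52) arrays.

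**Figure D1:**
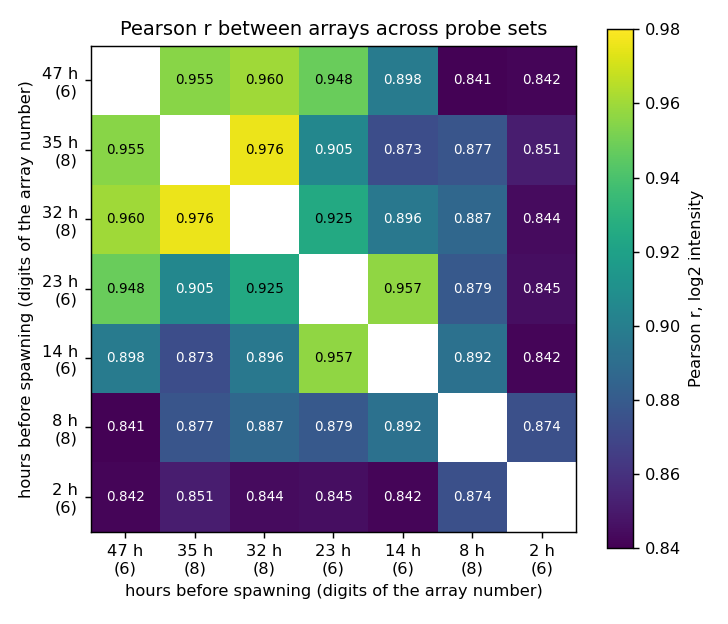
Pearson correlation of log2 intensity between each pair of the 7 arrays, across the 47773 probe sets above the filter, with hours before spawning and the number of digits of the array number on both axes. The 35 h and 32 h arrays have the highest value (0.976), and the values of the 2 h array with all others lie at 0.842 to 0.874.

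**Figure D2:**
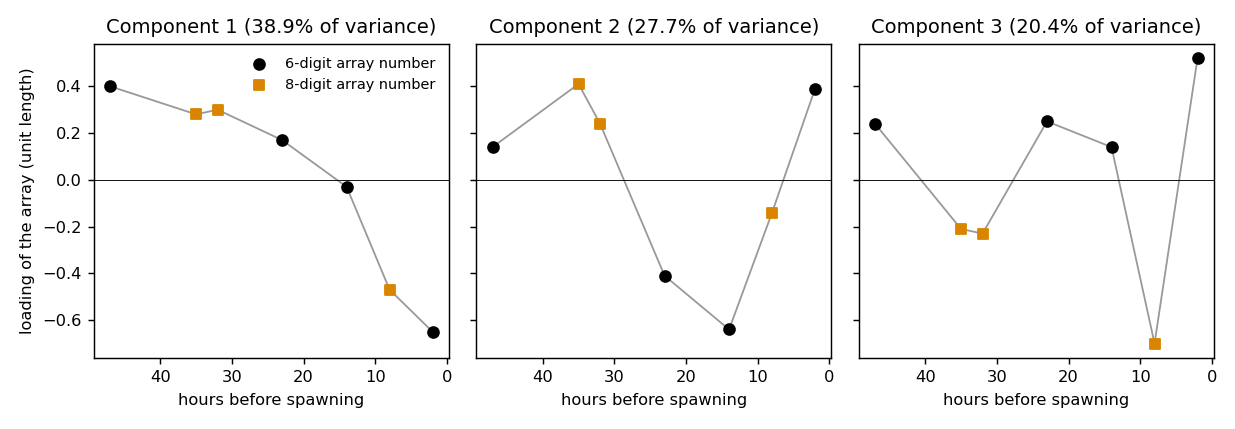
Loading of each array (unit length, no unit) on the first 3 principal components against hours before spawning, with circles for 6-digit and squares for 8-digit array numbers. Component 1 falls from 0.40 at 47 h to -0.65 at 2 h, component 2 is lowest at 14 h (-0.64), and component 3 has opposite signs in the 2 array-number series.

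With the times of the per-array files, expression differed most between consecutive time points in the last 14 h before spawning. Between 14 h and 8 h, 1442 probe sets were at least 4-fold higher and 1627 at least 4-fold lower at the later time, together 6.42% of those kept. Between 8 h and 2 h, 2101 were higher and 1842 lower, or 8.25%. The 3 h interval from 35 h to 32 h held 194 higher and 175 lower probe sets, which is the smallest count and serves as the nearest measure of array-to-array spread. In that interval 95% of probe sets differed by less than 1.02 on the log2 scale. The next largest counts lay between 32 h and 23 h, with 990 higher and 785 lower, against 549 and 401 between 23 h and 14 h and 401 and 263 between 47 h and 35 h. The 35 h to 32 h and 23 h to 14 h intervals lie within an array-number series, and the other 4, among them the 3 with the highest counts, compare arrays of different series. Counts did not follow the series throughout, since the 47 h to 35 h interval, across series, held 664 differences, the 23 h to 14 h interval, within one, held 950, and the 8 h array differed from the 32 h array of its own series in 3207. Centring each array on its median, an alternative added after the data were seen, removed log2 shifts of 0.118 from 32 h to 23 h, -0.187 from 14 h to 8 h and 0.192 from 8 h to 2 h and turned the balance of directions. The shifts followed the array-number series, at -0.107 in the other interval across series (47 h to 35 h) and at -0.022 and -0.033 in those within one, and the 3 arrays of the 8-digit series had the lowest medians. Centring gave 849 higher and 941 lower for 32 h to 23 h, 1769 higher and 1256 lower for 14 h to 8 h, and 1710 higher and 2290 lower for 8 h to 2 h. With the times of the series table the counts of 4-fold differences were 1382, 950, 4389, 4369, 3207 and 3574 in the 6 intervals in time order, so that the highest counts then lay between 32 h and 14 h and not in the last 14 h.

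**Figure D3:**
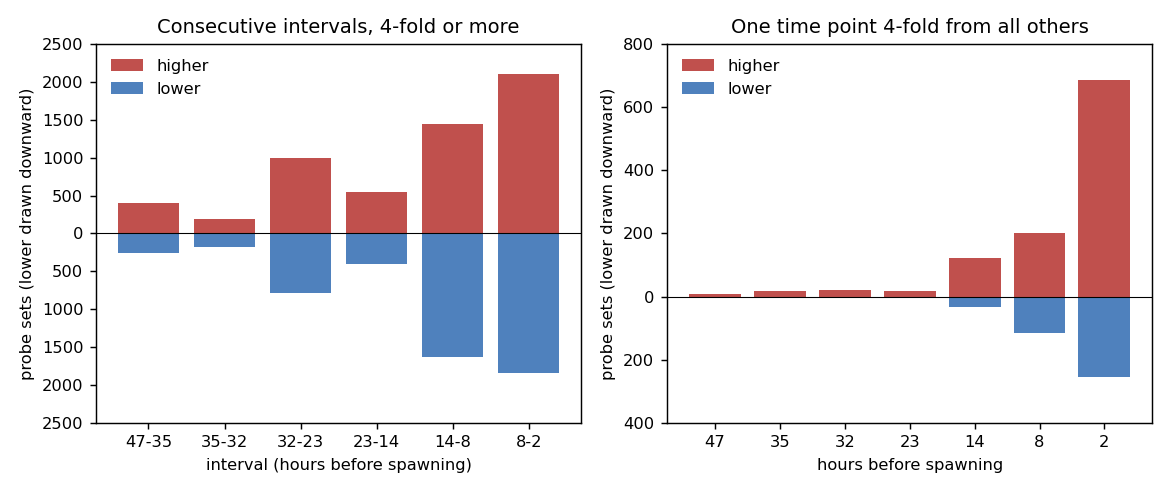
Left, number of probe sets at least 4-fold higher (upward bars) or lower (downward bars) at the later time of each consecutive interval; right, number at least 4-fold above or below all 6 other arrays at 1 time point. Each time point is 1 array; the counts are largest from 8 h to 2 h (2101 and 1842, or 1710 and 2290 with each array centred on its median) and at 2 h (686 and 256).

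Groups of probe sets could be set apart by the times at which they were high or low. Of the 47773 probe sets, 12319 (25.8%) had at least a 4-fold range over the 7 arrays and 16523 (34.6%) stayed within a 2-fold range. Among the 12319, the highest level fell at 2 h in 24.8%, at 8 h in 17.8% and at 14 h in 15.4%, and at 32 h in 6.5%. The lowest level fell at 2 h in 25.2% and at 8 h in 23.0%. A group of 686 probe sets stood at least 4-fold above every other array at 2 h alone, and 256 stood at least 4-fold below. At 8 h alone the corresponding groups held 201 and 115 probe sets and at 14 h alone 121 and 33. The 4 earlier arrays had 8 to 20 such highs each and at most 5 lows. An array with a close neighbour can hardly stand apart from all others, so this measure favours arrays without one. The 35 h and 32 h arrays correlated at 0.976, and the 2 h array with none above 0.874. How far the spacing of the samples shaped these counts was not tested. With times from the series table the 942 probe sets of the 2 h array belonged to 23 h, and the 154 of the 14 h array to 32 h.

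Other groups differed over a run of neighbouring times, a description chosen after the values were seen. At 8 h and 2 h together, 264 probe sets were at least 4-fold above all 5 earlier arrays and 118 at least 4-fold below. From 23 h onward 107 were above and 103 below the 47, 35 and 32 h arrays. A transient group of 111 probe sets was at least 4-fold higher at 23, 14 and 8 h than at both the earlier times and 2 h, against 19 that were lower. Shorter transient groups of 65 and 45 probe sets were high at 14 h and 8 h and at 23 h and 14 h, with 18 and 13 low. From 14 h onward 45 were above and 32 below all earlier arrays. With times from the series table these 6 groups held 2, 19, 3, 6, 0 and 15 probe sets in the order given. In total there were 1105 separations of a probe set's arrays by 4-fold with 2 to 5 arrays on each side. A probe set with several such gaps counts at each of them, so these groups can overlap. Probe set OLAT0001S00016326, for example, is in the groups from 23 h onward and from 14 h onward. Of the 1105 separations, 971 (87.9%) formed a run of neighbouring times, against 170 (15.4%) in the order of the series table. The median was 240 over all 2520 orders, among which the per-array order and the table's order ranked at 22 and 1429. A steady course was less common, with 68 probe sets rising and 135 falling at every time point, where all possible orders of the arrays held 19.0 on average and the order in the series table held 47.

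The slope of expression on time was tested over the 7 arrays with limma, with the array-number series as a term. At an adjusted p below 0.05, 93 probe sets rose toward spawning and 220 fell. The median fitted change from 47 h to 2 h was 3.62 on the log2 scale among those that rose and -3.38 among those that fell. Probe set OLAT0001S00013910 rose by a fitted 9.99 ± 1.0 (SE; adjusted p = 0.0321, limma, 7 arrays), from an intensity of 137 at 47 h to 6309 at 23 h and 47210 at 2 h. Probe set OLAT0001S00016326 rose by 8.60 ± 0.81 (SE; adjusted p = 0.0283, limma), from 76 at 47 h through 620 at 23 h and 5511 at 14 h to 14532 at 2 h. Probe set K_OLAT0000S00022020 changed by -8.48 ± 0.98 (SE; adjusted p = 0.0411, limma), from 7873 at 47 h through 751 at 23 h to 26 at 2 h. Probe set K_OLAT0000S00003018 changed by -8.74 ± 1.15 (SE; adjusted p = 0.0473, limma), lying at 9432 to 13333 from 47 h to 32 h and at 42 to 180 from 23 h onward; its adjusted p (limma) was 0.08 without the array-number term, 0.0501 without the filter, 0.0513 after quantile normalization, 0.0508 with an offset of 64 and 0.059 on the rank of time. These 4 have the largest fitted changes among the called probe sets. In each of the 4 the fitted change is larger than the measured one from 47 h to 2 h. For OLAT0001S00013910 the measured log2 values were 7.10 at 47 h and 15.53 at 2 h. The lowest intensities of the 4 lie near the filter threshold or below it, apart from the first. With an offset of 64 the fitted changes were 9.29, 7.44, -6.88 and -7.62 in the order given.

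The slope test measured the spread of single arrays about a line, so a real change of another shape counted as spread. It called 10798 probe sets at an unadjusted p below 0.05, where 2389 were expected by chance. Leaving out the 2 h array raised the called number from 313 to 2694, which held all 313. Leaving out any one of the other 6 arrays gave 0 called probe sets, with 6652 to 10862 at an unadjusted p below 0.05. With the times of the series table limma called 0, with 3036 at an unadjusted p below 0.05, and the fit without the array-number series also called 0, with 7020.

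A step between 23 h and 14 h, the interval in which the luteinizing hormone surge was placed from general knowledge of medaka, was tested in the same way. Limma called 10 probe sets as higher and 2 as lower at 14, 8 and 2 h than at 47, 35, 32 and 23 h, and 9183 passed an unadjusted p below 0.05. With a linear term for hours added, limma called 0, with 622 at an unadjusted p below 0.05. None of the 12 was among the 313 called for slope, but their slopes had the same signs as their steps, with adjusted p of 0.0656 to 0.129 (limma). Steps at the neighbouring intervals called more, with 119 higher and 257 lower for a step between 32 h and 23 h and 755 higher and 872 lower for a step between 14 h and 8 h. Whether these numbers differ from each other was not tested. The called number was 0 without the 47, 35, 32 or 8 h array and 22 (17 higher, 5 lower) without the 2 h array. It was 512 without the 23 h array (158 higher, 354 lower) and 1589 without the 14 h array (773 and 816), where more were lower than higher.

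Arrays 24 h apart share the time of day and, here, the array-number series, and were compared to set stage apart from both. At 23 h against 47 h, 751 probe sets were at least 4-fold higher and 631 at least 4-fold lower. At 8 h against 32 h, 1698 were higher and 1509 lower. Of the probe sets higher in the first pair 372 (49.5%) were also higher in the second, against 26.7 if the lists were independent, and of those lower 319 (50.6%) were also lower, against 19.9. These expectations take all 47773 probe sets as equally likely to change and so are probably too low, since only 12319 had a 4-fold range. Only 36 probe sets differed 4-fold in opposite directions. Across probe sets the log2 differences of the pairs, which share no array, correlated at r = 0.48 (Spearman's rho 0.40). With the times of the series table, which pair other arrays, more were shared, with 496 probe sets higher and 406 lower in both pairs. Probe sets are not independent. A paired limma fit of these 4 arrays, added after the data were seen and with 1 residual degree of freedom, called 0 probe sets (smallest adjusted p = 0.247), with 5430 at an unadjusted p below 0.05 against 2389 expected by chance.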

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

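Many counts depended on which deposited source gave the times. With the times of the series table, an alternative added after the data were seen for the counts without a test, the slope test called 0 probe sets with or without the array-number term. The interval counts became 1382 (47 to 35 h), 950 (35 to 32 h), 4389 (32 to 23 h), 4369 (23 to 14 h), 3207 (14 to 8 h) and 3574 (8 to 2 h), and the count shared by the 24 h pairs 902. Single-time-point counts became 154 at 32 h, 942 at 23 h, 20 at 14 h and 23 at 2 h. Separations fell to 2 (8 and 2 h), 19 (23 h onward), 3 (23, 14 and 8 h), 6 (14 and 8 h), 15 (14 h onward) and 0 (23 and 14 h), and probe sets rising or falling throughout to 47. With the table's times and the array-number term, as planned, the 4 named slopes kept their signs at 12.41, 12.03, -12.66 and -12.26 (adjusted p = 0.633 for each, limma). In that order all 6-digit arrays come before all 8-digit arrays, so the term overlaps with time and these slopes are poorly determined. With the table's times and no such term, which changes 2 choices at once and was added later, slopes reversed to -0.54 for OLAT0001S00013910, -0.42 for OLAT0001S00016326 and 1.92 for K_OLAT0000S00003018, none called. The step of the series table coincides with the array-number series, so it could not be fitted with that term. Without the term it called 8, sharing 0 with the 12.

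With the times of the per-array files, the slope test called 484 probe sets with an intensity-dependent robust prior, 480 with an offset of 64 and 553 with the last array at 5 h, sharing 294, 296 and 311 with the 313. Other alternatives that kept all 7 arrays gave 217 to 396. Leaving out 1 array gave 0 to 2694 for the slope, 0 without any array but the 2 h array. For the step it gave 0 to 1589. The step called 22 with the robust prior, 376 when placed between 32 h and 23 h, 1627 between 14 h and 8 h, and 0 (622 at an unadjusted p below 0.05, limma) with a linear term added; other settings gave 8 to 15. The alternative fits with the times of the per-array files kept the signs of the 4 named slopes, except that the filter at the 50th percentile removed K_OLAT0000S00022020.

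A 2-fold limit gave 6022, 2515, 8867, 3988, 12301 and 13100 probe sets in the 6 intervals in time order, and 2511 in both 24 h pairs. Unlike at 4-fold, more were then lower than higher from 47 h to 35 h (2613 higher, 3409 lower). The same held from 35 h to 32 h (1248 and 1267), from 23 h to 14 h (1879 and 2109) and in both 24 h pairs (1191 and 1320). The other intervals kept their balance of directions. The offset of 64 gave 305, 182, 1135, 625 and 1935 in the first 5 intervals, counts of 3 at 47 h, 10 at 35 h and 184 at 8 h for single time points, and 50 for the separation from 14 h onward. With this offset more were higher than lower from 14 h to 8 h (1018 and 917), unlike in the main counts. A log2 gap of 1 gave 188, 268, 92, 180, 627, 1818 and 3185 single-time-point probe sets in time order. At 8 h alone the balance then turned, with 907 above and 911 below. The same gap gave 1175, 751, 469, 394, 379 and 437 separations for 8 and 2 h, 23 h onward, 23 to 8 h, 14 and 8 h, 14 h onward, and 23 and 14 h. Unlike at a gap of 2, more were below than above from 23 h onward (292 above, 459 below) and from 14 h onward (164 and 215). The other separations kept their balance of directions. Without the filter the single-time-point counts at 23 h and 14 h were 41 and 267. The balance of directions then turned from 35 h to 32 h (224 higher, 226 lower) and from 23 h onward (107 above, 111 below). In each of these settings the 8 h to 2 h interval and the 2 h array held the highest counts. The gene list alternatives were not run, since the lists could not be matched. The paired fit of the 24 h pairs called 0 under each of its 4 alternatives, with 5254 to 6550 at an unadjusted p below 0.05 (limma). By replicate number, no paired analysis was possible because each time point has 1 array.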

Other observations

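All tests below were chosen, in the form given, after results that bear on them had been seen. No group holds more than 1 array, so no array was set against others of its own group.

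The 2 sets of deposited times make different predictions if follicles sampled close together are alike. The distance between neighbouring arrays (1 minus r, summed over the order) placed the order of the per-array files at rank 6 of the 2520 possible orders, and the order of the series table at rank 1356. Under the other filters the ranks were 5 to 9 and 1263 to 1358. By the number of steadily rising or falling probe sets with a 4-fold range, the per-array order was at rank 3 with 100 and the table's at rank 443 with 7. These values argue against the times of the series table, on the untested assumption that neighbours in time are alike, and a candidate explanation is that its columns were sorted by array number. An open point is that the order with the most steady probe sets of any size (266, against 203) put all 6-digit arrays before all 8-digit arrays. It is the order of the series table with its last 2 arrays exchanged, and 64 of its 266 had a 4-fold range.

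The 2 array-number series cannot be told apart from time of day, because the 35, 32 and 8 h arrays lie 8 to 11 h before the hour of spawning on their day and the other arrays do not. Each array was left out and placed between the remaining 6-digit arrays (0) and 8-digit arrays (1). A batch predicted a value of at most 0.25 for the 14 h array and time of day a value of at least 0.5. It lay at 0.20. The 23 h (0.08), 35 h (0.69) and 32 h (0.65) arrays also lay on their own side, but the 47 h (0.61), 2 h (0.72) and 8 h (0.26) arrays did not, so the measure does not place arrays reliably and decides for neither. The series separated 15 probe sets by 4-fold, against 382 for the 8 h and 2 h arrays together, a measure that would miss smaller shifts. The median was 1 over the 56 ways to part the arrays with 2 to 5 on each side. Among all 63 ways the series ranked at 16, so it parted more probe sets than most. As a term beside the slope, the series called 3 probe sets (limma), with 11506 at an unadjusted p below 0.05 against 10798 for the slope and 2389 expected by chance.

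The 2 h array held the most highs and lows at a single time point, 686 and 256. Noise of that array alone predicts no relation with the 8 h array, measured against the 35 h and 32 h arrays of its own series. The first form of this test took highs and lows together with a bound of 60% set before its value was known, and its 61.7% passed that bound against noise. The bound was replaced, and highs and lows were parted, once it was seen that probe sets in general were mostly lower at 8 h. Of the highs, 64.4% were also higher at 8 h. The share was 39.0% of all probe sets and 44.9% of other probe sets matched on their mean in the 6 other arrays. The matching took level alone and not how much a probe set varied. Among probe sets that differed 4-fold at 8 h against 32 h, more were higher (1698) than lower (1509), unlike probe sets in general. The excess of the highs over the matched share therefore does not by itself decide against noise of the 2 h array. Of the lows, 54.3% were also lower at 8 h, against 61.0% of all probe sets and 63.4% of matched ones. This share lies below the matched one, but the matching has the same limit here. The bound looked only for an excess, so the test does not decide on noise for the lows. A count of 925 highs and lows after the arrays were quantile normalized again does not decide on overall signal level. The 2 h median intensity (685) already lay within those of the other arrays (599 to 703). Normalizing again could therefore hardly have lowered the count by much. The follicle stage stays open and untested with 1 array at 2 h.

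Of 100 orders of the time points drawn from the 5040 possible, the real one included, 2 gave 313 or more called probe sets, and the highest other gave 1530. Few of the drawn orders thus gave as many calls as the real one. This share does not exclude chance, since the count rests on single arrays and is not the highest that an order can give. Why another order gave a count so far above the real one was not tested. For the step, too, chance could not be excluded. Of the 34 splits into 3 and 4 arrays that could be fitted, 4 gave 12 or more called probe sets, and the highest other gave 1808. That split put the 47, 23 and 14 h arrays together, which under the array-number term sets them against the 2 h array alone.

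The 2 classes of probe set identifier differed in how often they varied. A 4-fold range was found in 31.3% of 16940 kept probe sets with the prefix K_OLAT0000S and in 22.8% of 30833 with the prefix OLAT0001S. Among 4 equal classes of mean level the shares were 45.5% and 43.7% in the lowest class and 13.9% and 8.9% in the highest. What the prefixes stand for is not given in the sources used here.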
